A study of Mus musculus with 5 samples.

How the data were processed

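Liver RNA of 5 male mice homozygous for the eyeless (eyl) mutation of Pitx3, a homeodomain transcription factor gene known for its roles in lens and midbrain dopamine neurons, was measured on 2-colour cDNA arrays. Per the labels, the mice were 17 weeks old and each array carried the RNA of 1 mutant animal beside an RNA pool from wild-type mice. The mutant RNA was labelled with Cy5 on replicates 1, 2 and 4 and with Cy3 on replicates 3 and 5, the dye swaps, per the labels. The number of animals in the pool is 4 per the sample labels and 6 per the labels' labelling protocol, and this difference stays open. RNA was isolated on columns from homogenised organs, and 20 µg of total RNA were labelled indirectly after reverse transcription, per the labels' protocols. The scanner, the background correction and the normalization are not given in the sources used here.

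The deposited values are log2 ratios of the 2 channels of an array, with 20355 probes per array and 73450 values in all. That they are log2 values was read from the deposited values themselves: the most frequent values lie in steps of exactly 1. They lie at 1 constant per array plus the log2 of ratios of small whole numbers, such as 2 or 3. The constants were -0.19, -0.33, -0.15, 0.46 and -0.08 for replicates 1 to 5. For these values, the form leaves room for 1 scaling factor per array and for no correction that depends on the brightness of a spot. Values at ratios of whole numbers up to 20 made up 20.1% to 29.6% of an array's measured values. When the same values were shifted by random amounts, 8.4% to 10.0% lay at such ratios. Part of the matches may thus be coincidence. For such matches and for the other values, a correction of that kind cannot be excluded from the form. The array medians were -0.19, -0.04, -0.00, 0.11 and 0.23, so the deposited values were not centred on the median. No value table column was left unused (0 columns).

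On each array, between 80 and 213 values were identical and lay at the array's constant plus or minus the log2 of 100000. These 788 values, on 768 probes, were read as a code for a ratio without a measurable denominator and were set to missing. The design fixed before the data were examined had not foreseen such a code, and keeping the coded values is an alternative added after seeing the data. The code was positive on each array with the mutant in Cy5 and negative on each array with the mutant in Cy3. A software code for an unmeasurable denominator would keep 1 sign, so the swapped arrays were read as turned before deposit and all 5 arrays as running the same way. Whether that way is mutant over pool is likely but not known: it rests on the labels, which list the mutant as channel 1, and on the customary ratio of Cy5 over Cy3. A positive log2 ratio is read here as higher in the mutant.

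Gene names came from the platform's annotation table. Of the probes, 14030 carried 1 gene symbol, 5 carried several and 6320 are unnamed here; 9930 genes were named. A gene table of the mouse assembly GRCm38.p6, used only for names and for neighbouring genes, held the gene identifiers of 13994 probes and changed 0 symbols. The placing of names on rows was checked on 267 probes of 4 lists of transcripts abundant in liver (ribosomal proteins, oxidative phosphorylation, secreted hepatocyte proteins, urea cycle and amino acid catabolism). Their median SD between arrays was 0.60, against 0.91 to 1.22 for rows shifted by 1 to 6 places. For 3004 genes with at least 2 probes, the number of arrays measuring the first probe had a Spearman rho of 0.030 with that of the next probe, across genes. Between the SDs of 2 probes of the same gene, for 52 genes of the 4 lists, rho was -0.191. Names are thus borne out for these lists as sets, and not for a single probe or gene.

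A probe entered the test with values on at least 4 arrays and in both dye orientations, which left 11300 probes. limma (version 3.58.1, R 4.3.3) fitted an intercept and a dye term to the log2 ratios with lmFit and eBayes. The intercept weights both dye orientations equally and is called the mutant coefficient. The dye coefficient is the mean over Cy5 arrays minus the mean over Cy3 arrays, divided by 2. Each fit had up to 3 residual degrees of freedom, and limma's prior added 2.24 with a prior SD of 0.85. Since no wild-type animal was hybridised against the pool, the pool is 1 control sample and the ratio was tested against 0. The spread between wild-type animals is left out of every error given here. Adjusted p-values are Benjamini-Hochberg values, and a call needs an adjusted p under 0.05.

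Gene lists (34, fixed before the data were examined) were tested on gene-level values, probes of a gene averaged. The test was limma's competitive camera test with a preset correlation of 0.01 between genes, run on the moderated statistics because of missing values. Camera with an estimated correlation and fry were run beside it on genes measured on all 5 arrays. A list needed at least 5 measured genes, which 33 lists had. The rule for naming genes was also fixed beforehand. It takes called genes first and, if fewer than 10 are called, the 10 genes each way with the lowest unadjusted p and the same sign on all arrays, given as values. It adds up to 2 members with the lowest p from each list not called, Pitx3, and the 3 genes each way with the lowest p for the dye coefficient.

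The fit was tested on simulated data with normal noise, at limma's SD of each real probe after its prior, and with the real missing values. There were 11300 probes and 5 runs, with 50 probes changed at each size per run. limma called 0% of probes changed 2-fold, 16.4% of those changed 4-fold, 56.8% at 8-fold and 80.0% at 16-fold. Of the 55500 unchanged probe tests, 18 were called. The list test found a list of 18 genes shifted by a log2 of 1 and called 0 other lists. Noise was drawn independently for each gene, so this does not cover lists whose members vary together. The shift was larger than any median of the tested lists, which were at most 0.56 in size. The number of arrays, 5, limits the precision.

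The alternatives fixed before the data were examined were no dye term, replicates 3 and 5 turned, median centring with and without scaling, values required on all 5 or on at least 3 arrays, robust eBayes, array weights, an added 1.5-fold minimum, a one-class SAM statistic with the 16 sign patterns, gene averages, probes kept separate, and leaving out each array. Alternatives added after seeing the data were keeping coded values, leaving out values at ratios of whole numbers up to 20 (within 0.001 on the log2 scale), removing a running median over 101 probe numbers, and the preset correlation over genes on all 5 arrays. Random gene sets (10000) were matched on 20 classes of spread between arrays and on the number of arrays. Estimated correlations were set against those of 1000 random gene sets of each list's size. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for the remaining steps.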

Results

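Expression profiles of the liver were compared between 5 male mice homozygous for the Pitx3 eyeless mutation and a wild-type RNA pool, with 1 array per mutant animal. The comparison asks which liver transcripts differ in the mutant line. Of 20355 probes, 6364 had a measured value on all 5 arrays, 4936 on 4 arrays and 187 on 0 arrays. Missing values made up 21.5% of the probes on replicate 1, 31.2% on replicate 2, 29.3% on replicate 3, 32.3% on replicate 4 and 24.9% on replicate 5. The SD of the log2 ratios over all probes of an array lay between 1.51 and 1.72. Between 35.9% and 46.0% of an array's values were over 2-fold away from its median.

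In the mutant livers, no transcript differed from the wild-type pool after correction for multiple testing: limma called 0 of 11300 probes, and 0 of 6706 genes when probes of a gene were averaged. The lowest adjusted p from limma was 0.999 for probes and 0.998 for genes. At an unadjusted p under 0.05 there were 470 probes (4.16%), 266 with higher and 204 with lower values in the mutant, where chance alone gives 5%. Without replicate 4 this balance turned, at 243 higher and 352 lower, and without replicate 1 it widened, at 551 higher and 245 lower. A one-class SAM statistic also called 0 probes, with a lowest false discovery rate of 1.03. Signs are given as mutant over pool, which is the likely and not the known direction. In the simulated data, probes changed 4-fold were called in 16.4% and probes changed 2-fold in 0% of cases. These rates hold for the simulated noise and share of changed probes only.

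Among probes with the same sign on all 5 arrays, the lowest unadjusted p on the higher side belonged to Ndufs3, a core subunit of mitochondrial complex I. Its log2 ratio was 2.42 ± 0.35 (SE, 5 arrays), ranging from 0.39 on replicate 2 to 4.24 on replicate 5. Cnpy1 had a log2 ratio of 2.36 ± 0.38 and Cdc16, a subunit of the anaphase-promoting complex, 2.67 ± 0.47. Tcte3 stood at 1.97 ± 0.38, 1700071K01Rik at 1.46 ± 0.29 and Ccdc186 at 1.37 ± 0.29. Slc66a1, a lysosomal amino acid exporter, had 1.11 ± 0.28 and Nbn, a component of the complex that senses DNA double-strand breaks, 1.21 ± 0.32. Slc6a17, an amino acid transporter best known from neurons, had 1.44 ± 0.41 and the chromatin-binding Psip1 1.34 ± 0.39. These 10 genes are given as values, since limma's adjusted p was 0.999 for each.

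On the lower side the lowest unadjusted p belonged to Parp16, an ADP-ribosyltransferase of the endoplasmic reticulum, with a log2 ratio of -1.96 ± 0.30 (SE, 5 arrays) and array values from -2.60 to -1.51. Rps19bp1 had -3.27 ± 0.68 and Shmt2, the mitochondrial serine hydroxymethyltransferase, -2.03 ± 0.45. The transcriptional repressor Bcl6 had -1.10 ± 0.30, Tcp11l2 -1.33 ± 0.36 and Ubl4b -1.15 ± 0.32. Il6ra, the interleukin 6 receptor, had -2.78 ± 0.93, with array values from -5.57 to -0.71. Prepl had -2.01 ± 0.68, the splicing factor Cwc22 -1.69 ± 0.59 and Tat, the tyrosine aminotransferase of the liver, -0.78 ± 0.27. The adjusted p from limma was 0.999 for each of these 10 genes as well. Genes with 1 sign on all 5 arrays numbered 166 above and 108 below 0, from 277 of 4594 named probes measured on all 5. Over all probes measured on all 5 arrays the share with 1 sign was 5.99%, where chance gives 6.25%.

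**Figure D1:**
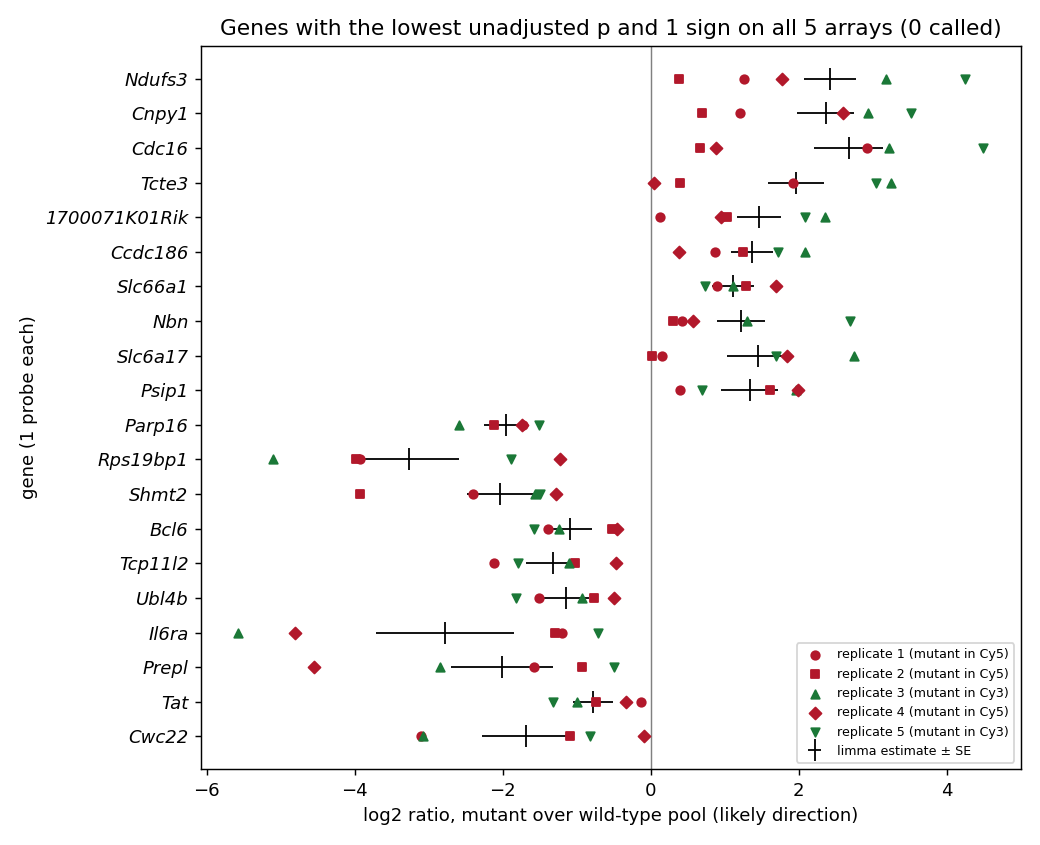
Log2 ratios of mutant over wild-type pool (likely direction) for the 20 named genes, 1 point per array, coloured by the dye of the mutant RNA, with limma's estimate and its SE in black. All points of a gene lie on 1 side of 0 because the genes were chosen that way; Ndufs3 spans 0.39 to 4.24 and Parp16 -2.60 to -1.51.

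Other probes of the same genes did not share these values. A further probe of Cdc16 stood at -0.43 ± 0.50, of Tcte3 at -0.28 ± 0.52, of Slc6a17 at -0.06 ± 0.41 and of Psip1 at 0.01 ± 0.28. The other 3 probes of Ccdc186 lay between -0.48 and 0.15. For Ubl4b the other probe had 0.82 ± 0.63, and for Bcl6 it had -0.42 ± 1.09. The other probe of Parp16 had -2.01 ± 0.98, but its arrays ran from -5.57 to 3.08. Over the 1248 genes with at least 2 tested probes, the mutant coefficients of a pair had the same sign in 51.3% and a Pearson r of 0.009 across genes, which are not independent replicates.

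No probe carried the name Pitx3 (0 probes), so the mutated gene was not analysed here. Its neighbours were: of the 197 genes on either side of Pitx3 in the reference order, 82 were measured, 46 above and 36 below 0, with a median log2 ratio of 0.04 (camera adjusted p 0.733). The members with the lowest p were Ldb1, a LIM domain-binding cofactor, at 2.16 ± 0.45 and Slc18a2, the vesicular monoamine transporter, at 2.07 ± 0.63. Each was measured on 4 arrays. Array values of Ldb1 ran from -0.34 to 4.47, and its dye coefficient was 1.74. Of the 8 measured members of the list of PITX3 and its described targets, 5 lay above and 3 below 0 (median 0.32, camera adjusted p 0.638); the median was -0.08 without replicate 5 and 0.73 (adjusted p 0.0650) without simple-fraction values. They included Slc18a2 and Nr4a2, a partner of PITX3 in dopamine neurons, at 1.22 ± 0.55. Array values of Nr4a2 ran from -1.97 to 3.94, and its dye coefficient, -1.62, was larger in size. Array values of Slc18a2 had the sign of its estimate on 2 of 4 arrays, with 4.57 on replicate 3, its only array with the mutant in Cy3, and -1.76 to 0.91 on the others.

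Of the 33 gene lists tested, 0 were called by camera, and 0 list members passed when adjusted over all genes. The lowest adjusted p, 0.0936, was shared by 6 lists, all with medians below 0. Some of these lists share members and so are not independent. Tat is in the gluconeogenesis and urea cycle lists, and Asl and Ass1 are in the periportal and urea cycle lists. Ribosomal protein genes had 36 of 46 measured members below 0 and a median log2 ratio of -0.15, with Rpl39l at -2.62 ± 1.12 and Rps6 at -0.70 ± 0.38. Oxidative phosphorylation genes had 43 of 58 below 0 and a median of -0.16. The members with the lowest p were Ndufs3, against that direction at 2.42 ± 0.35, and Uqcr11 of complex III at -1.04 ± 0.39. With an estimated correlation between members, the adjusted p was 0.799 for ribosomal proteins and 0.865 for oxidative phosphorylation. Adjusted over the list alone, Ndufs3 passed (limma adjusted p 0.0420), and no other member of these lists did. Each of the 33 lists was adjusted alone in this way, so chance may give a pass in some list. The values of Ndufs3 were 3.18 and 4.24 with the mutant in Cy3 against 0.39 to 1.77 in Cy5. It left the test when simple-fraction values were left out.

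The remaining lists at an adjusted p of 0.0936 belong to hepatocyte metabolism and to the clock. Genes of gluconeogenesis and glucose handling had 7 of 8 members below 0 (median -0.20), among them Tat at -0.78 ± 0.28 and Gpt, alanine aminotransferase, at -0.59 ± 0.45. Urea cycle and amino acid catabolism had 14 of 22 below 0 (median -0.16), with Haao at 0.85 ± 0.28 above 0. Periportal hepatocyte markers had 8 of 10 below 0 (median -0.12), with the urea cycle enzymes Asl at -0.68 ± 0.27 and Ass1 at -0.82 ± 0.34. Circadian clock and output genes had 10 of 14 below 0 (median -0.18), with Tef at -1.07 ± 0.43 and Per3 at -0.82 ± 0.39. With an estimated correlation the adjusted p was 0.758 for each of these 4 lists. Without replicate 1, the median of which lay above 0 for ribosomal proteins (0.21), oxidative phosphorylation (0.30), gluconeogenesis (0.39) and the urea cycle (0.20), camera called these 4 lists. Their lowest adjusted p was then 0.00342, and over the 16 settings with a row for it the ribosomal protein list ranged from 0.00342 to 0.866. Ribosomal proteins were also called without replicate 5 (camera adjusted p 0.0486), but not without replicate 2 (median -0.02, adjusted p 0.717) or replicate 3 (median 0.00, adjusted p 0.512). When values on all 5 arrays were required, 4 lists were called, and 0 on the same genes with an estimated correlation.

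**Figure D2:**
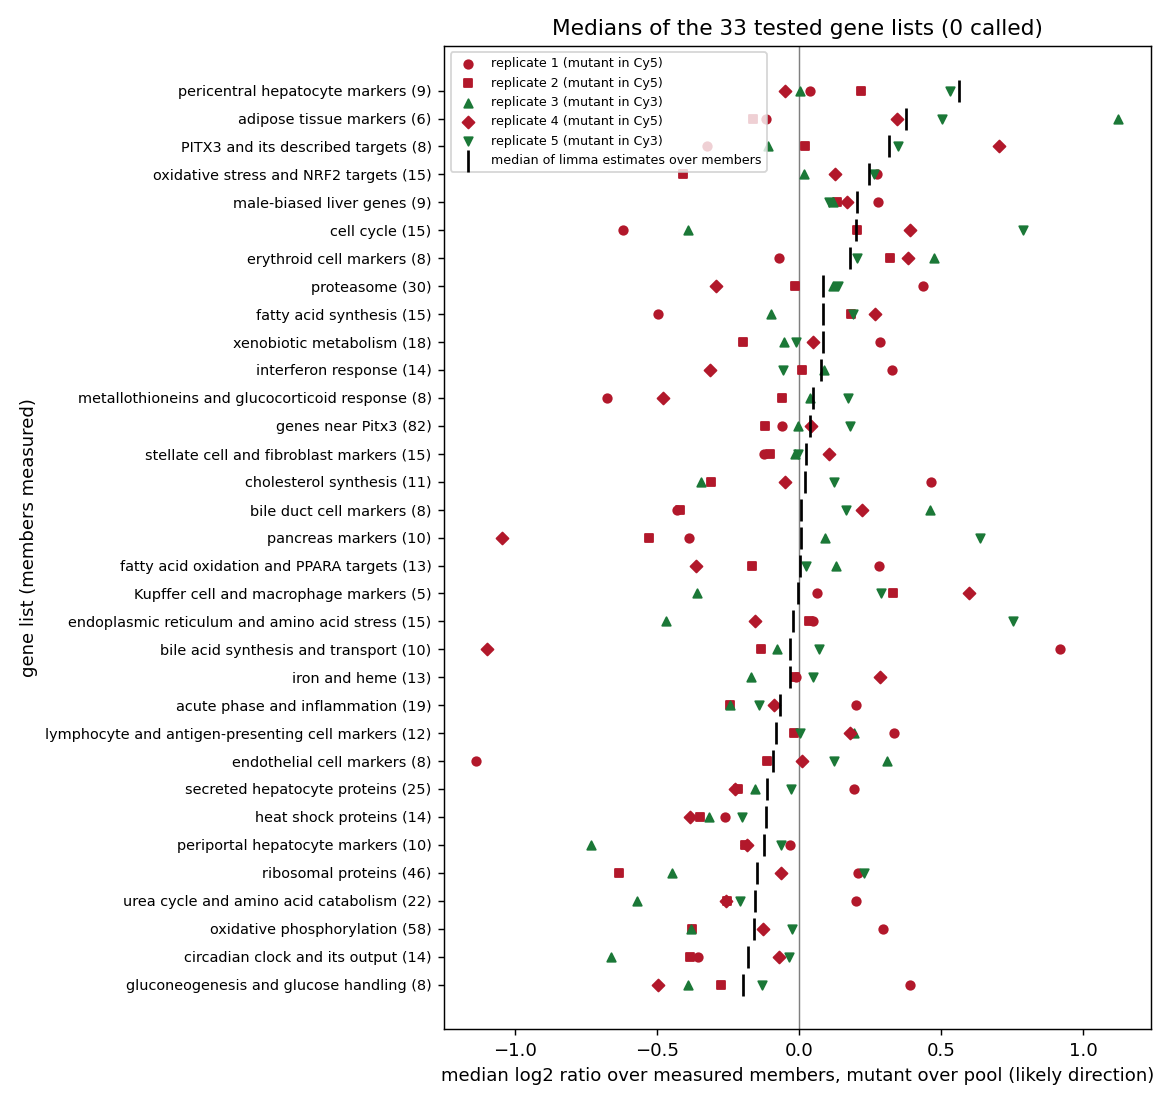
Median log2 ratio of mutant over wild-type pool (likely direction) over the measured members of each tested list, 1 point per array, coloured by the dye of the mutant RNA, with the median of limma's gene estimates as a black bar. Ribosomal protein medians lie at 0.21 on replicate 1 and -0.63 on replicate 2, a spread wider than the list's median of -0.15.

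Other hepatocyte functions gave no call either. Pericentral markers had 6 of 9 members above 0 (median 0.56, and 0.27 without replicate 4; camera adjusted p 0.211), with the aldehyde dehydrogenase Aldh3a2 at 0.79 ± 0.29 and glutamine synthetase, Glul, at 0.65 ± 0.28. The list's medians on single arrays ran from -0.05 on replicate 4 to 0.53 on replicate 5, all under 0.56. Glul had the sign of its estimate on 3 of 5 arrays, and its dye coefficient, -0.80, was larger in size. Secreted hepatocyte proteins had 17 of 25 below 0 (median -0.11, adjusted p 0.396), with Igfbp2 at -0.80 ± 0.32 and the iron carrier Trf at 0.90 ± 0.42. Xenobiotic metabolism had 10 of 18 above 0 (median 0.08, adjusted p 0.827), with aldehyde oxidase Aox3 at 1.22 ± 0.35 and Cyp2d10 at 2.30 ± 0.68. Male-biased genes had 5 of 9 above 0 (median 0.21, adjusted p 0.733), with the sterol hydroxylase Cyp7b1 at 0.70 ± 0.34 and Nat8 at 1.24 ± 0.79, the latter with 1 array in Cy3. Bile acid genes had 6 of 10 below 0 (median -0.03, adjusted p 0.827), with Cyp7b1 again and the bile acid receptor gene Nr1h4 at 0.62 ± 0.40. Of the female-biased list, 3 genes (Cux2, Lpl and Prom1) were measured, too few for the test.

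Lipid lists gave no call. Cholesterol synthesis had 6 of 11 members above 0 (median 0.02, camera adjusted p 0.894), with Tm7sf2 at 0.26 ± 0.27 and Srebf2, a transcription factor of the pathway, at -0.27 ± 0.30. Fatty acid synthesis had 8 of 15 above 0 (median 0.09, adjusted p 0.753), with Thrsp at -1.09 ± 0.37 and the elongase Elovl5 at 0.46 ± 0.27. Fatty acid oxidation and PPARA targets had 7 of 13 above 0 (median 0.00, adjusted p 0.733), with the lipid droplet protein gene Plin2 at 1.28 ± 0.44 and the fatty acid binding protein gene Fabp1 at 0.66 ± 0.39. Adipose tissue markers had 6 of 6 above 0 (median 0.38, adjusted p 0.263). The adiponectin gene Adipoq stood at 1.13 ± 0.79, with arrays from -3.39 to 6.12 and a larger dye coefficient of -3.05, and lipoprotein lipase, Lpl, at 0.44 ± 0.35.

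Stress and inflammation lists held values of either sign. Acute phase genes had 12 of 19 members below 0 (median -0.07, camera adjusted p 0.211), with Il6ra at -2.78 ± 0.92 and ceruloplasmin, Cp, at 1.03 ± 0.35. Array values of Cp were 2.81 and 1.16 with the mutant in Cy3 and -0.09 to 0.35 in Cy5. Heat shock protein genes had 10 of 14 below 0 (median -0.12, adjusted p 0.263), with Hspe1 at -2.02 ± 0.90 and Fkbp4 at -0.53 ± 0.27. Genes of endoplasmic reticulum and amino acid stress had 8 of 15 below 0 (median -0.02, adjusted p 0.827), with asparagine synthetase, Asns, at -1.52 ± 0.41 and Dnajc3 at 1.09 ± 0.45. Array values of Dnajc3 were -0.97 and -1.36 with the mutant in Cy5 and 2.40 and 4.30 in Cy3, and its dye coefficient, -2.26, was larger in size. NRF2 targets and oxidative stress genes had 12 of 15 above 0 (median 0.25, adjusted p 0.559), with Sod2 at -0.75 ± 0.37 and Gclm, of glutathione synthesis, at 0.45 ± 0.26. Metallothioneins and glucocorticoid response genes had 5 of 8 above 0 (median 0.05, adjusted p 0.615), with Tat and Mt2, the latter at -1.0 ± 0.49. Interferon response genes had 9 of 14 above 0 (median 0.08, adjusted p 0.894), with Irf1 at 0.41 ± 0.29 and B2m at 0.33 ± 0.29. Proteasome genes had 19 of 30 above 0 (median 0.09, adjusted p 0.908), with Psma5 at -2.29 ± 0.56 and Psmd2 at 0.87 ± 0.39. Cell cycle genes had 9 of 15 above 0 (median 0.20, adjusted p 0.827), with the replication helicase gene Mcm6 at -1.69 ± 0.38 and Cdc20 at 1.48 ± 0.70. Psma5 and Mcm6 rest largely on their only array with the mutant in Cy3, at -4.37 on replicate 5 and -3.05 on replicate 3, against -0.84 to 1.05 and -0.62 to -0.07 on the others.

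Markers of other cell types in or near the liver were not called. Kupffer cell and macrophage markers had 3 of 5 members below 0 (median -0.00, camera adjusted p 0.827). The cathepsin gene Ctss, at 2.41 ± 0.48 on 4 arrays, passed when adjusted over the list alone (limma adjusted p 0.0276). With 33 lists each adjusted alone, chance may give such a pass. It also rests largely on 1 array: Ctss had 3.94 on replicate 3, its only array with the mutant in Cy3, and 0.23 to 1.78 on the others. Lysozyme, Lyz2, stood at -0.39 ± 0.30. Erythroid markers had 7 of 8 above 0 (median 0.18, adjusted p 0.263), with the carbonic anhydrase genes Car1 at 1.74 ± 0.86 and Car2 at 0.61 ± 0.39. Iron and heme genes had 8 of 13 below 0 (median -0.03, adjusted p 0.894), led by Cp and Trf. Lymphocyte markers had 6 of 12 above 0 (median -0.08, adjusted p 0.974), with the T cell genes Cd8a at 1.26 ± 0.42 and Cd3g at 1.69 ± 0.93. Stellate cell markers had 9 of 15 above 0 (median 0.02, adjusted p 0.827), with the collagen genes Col1a1 at 0.62 ± 0.37 and Col6a1 at 0.67 ± 0.41, the latter with 1 array in Cy3. Endothelial markers had 4 of 8 above 0 (median -0.09, adjusted p 0.864), with Stab1 at 0.94 ± 0.73 and Vwf at -0.55 ± 0.43. Bile duct markers had 5 of 8 above 0 (median 0.01, adjusted p 0.733), with Sox9 at 0.64 ± 0.32 and Cftr at 1.17 ± 0.59. Pancreas markers had 5 of 10 above 0 (median 0.01, adjusted p 0.733), with Ctrl at -1.0 ± 0.50 and Pnliprp1 at -0.87 ± 0.64.

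Median, mean and test differed in sign for 11 of the lists. These were cholesterol synthesis, fatty acid synthesis, bile acids, metallothioneins, endoplasmic reticulum stress, iron and heme, Kupffer cells, lymphocytes, endothelial cells, pancreas and proteasome. No direction is read for them. Leaving out 1 array turned the sign of the median of 17 of the 33 lists, and for all 33 some left-out array turned it or moved it over 1.5 times. Of the 60 genes given from the lists, 14 had an unadjusted p under 0.05 in limma for the dye coefficient. It was larger in size than the mutant coefficient for 8 of them: Dnajc3, Glul, Slc18a2, Nr4a2, Col1a1, Vwf, Sox9 and Adipoq. The estimate's sign was seen on only 2 arrays for 5 genes: Dnajc3, Slc18a2, Col1a1, Stab1 and Sox9.

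The genes given for the dye coefficient were chosen for a low p and so differ between dyes by that choice. Fut10, a fucosyltransferase gene, had a dye coefficient of -2.55 ± 0.30 (SE), with values between -2.81 and -1.92 where the mutant was in Cy5 and of 2.99 and 2.27 where it was in Cy3. For 2610528J11Rik the coefficient was -3.04 ± 0.37 and for Eif3c, a translation initiation factor subunit, -3.67 ± 0.35. On the other side stood Ydjc at 3.48 ± 0.50, Srd5a3 at 1.90 ± 0.36 and Rasgrp3 at 2.14 ± 0.36. Ydjc and Rasgrp3 each rest on 1 array with the mutant in Cy3, and the other probe of Srd5a3 had a dye coefficient of -0.03 ± 0.71. limma called 0 of 11300 probes for this coefficient (lowest adjusted p 0.429), and 834 probes (7.38%) had an unadjusted p under 0.05, 168 above and 666 below 0. These are more than the 470 of the mutant coefficient.

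Signs coincided between animals no more often than chance gives. On the 3 arrays with the mutant in Cy5, 24.7% of 8421 probes had 1 sign on all 3, where chance gives 25%. On all 5 arrays, 381 of 6364 probes (5.99%) had 1 sign, where chance gives 6.25%. With arrays centred on their medians, the shares were 23.2% on the 3 arrays and 4.92% on all 5. The chance values take arrays as independent, although all share the wild-type pool. The median size of the mean log2 ratio over these 3 arrays was 0.39, and 18.1% of the probes exceeded 2-fold, but limma called 0 of them (410 at an unadjusted p under 0.05). The correlation across probes averaged 0.049 over the 4 pairs of arrays with like dye orientation, from -0.014 to 0.114. Over the 6 pairs with opposite orientation it averaged -0.084, from -0.251 between replicates 1 and 5 to -0.011. No pair lay under -0.3.

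**Figure D3:**
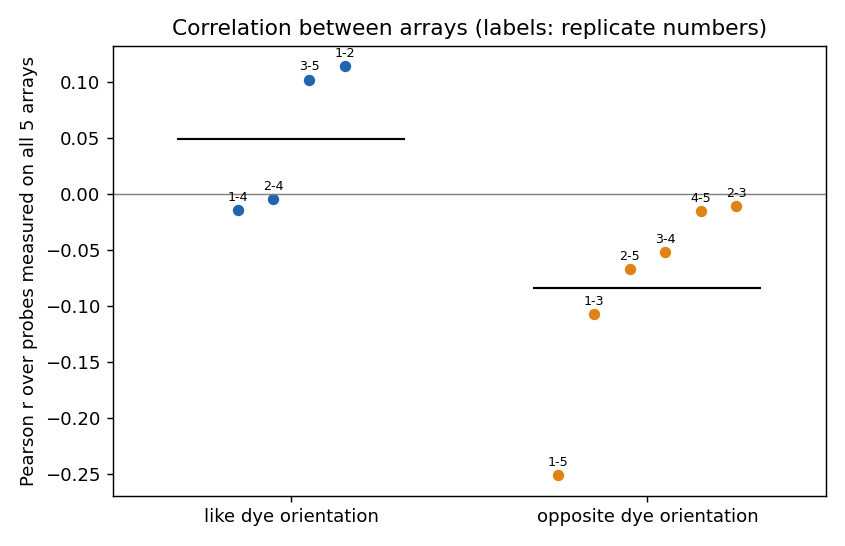
Pearson correlation of log2 ratios across the 6364 probes measured on all 5 arrays, for each pair of arrays, by whether the mutant RNA carried the same dye; black lines are means. Like pairs average 0.049 and opposite pairs -0.084.

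Liver genes known to move with feeding, time of day, stress or hormones were used to see which coefficient carried the animals. Over 90 such genes, the mean square of the mutant coefficient was 0.880 times that of the dye coefficient, against 0.656 for all genes, at the 84.6th percentile of 10000 random lists. This lies inside the range from 5 to 95 that had been set as open. With values required on all 5 arrays the percentile was 98.0. No direction is read from either percentile. Variation that is independent between animals enters both coefficients alike, so it cannot tell them apart. Only a difference from the pool shared by the arrays could.

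**Figure D4:**
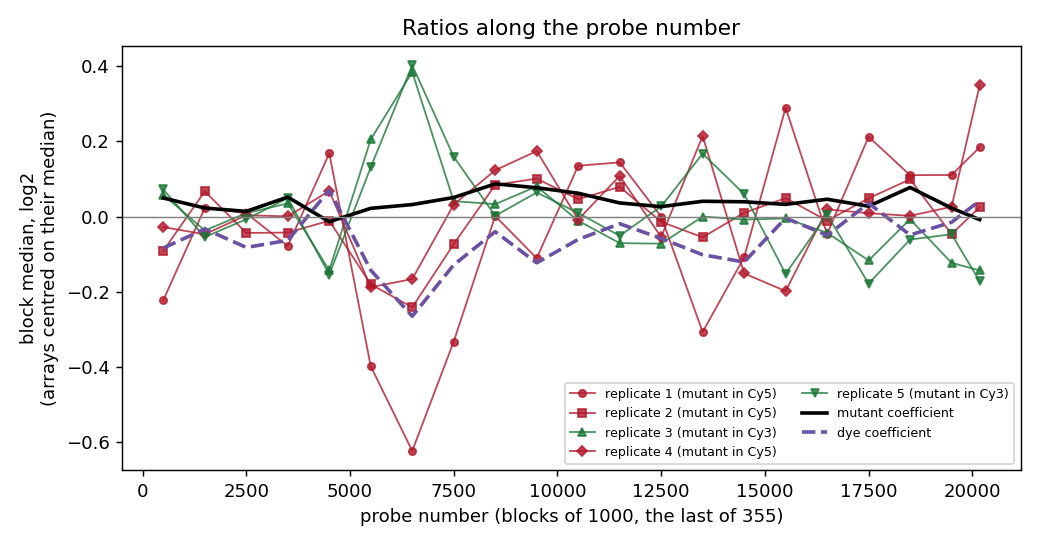
Median log2 ratio in blocks of probe numbers for each array (centred on its median), with the block medians of the mutant coefficient (solid black) and the dye coefficient (dashed). In the block from 6001 to 7000, replicate 1 lies at -0.62 and replicates 3 and 5 at 0.38 and 0.40, while the mutant coefficient lies at 0.03.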

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

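The tests of dye bias, of unturned arrays, of other choices of arrays and of members varying together were chosen after the result was seen. Matched random sets had been planned beforehand with another measure, the number of sets with a median as low; it is not used, since the lists were picked for their low p, and the sets' typical median was chosen in its place after the result was seen.

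Of 122 reported results with 4 or 5 array values, 2 had an array far from the others, where chance gives about 1 in 20. The median of the periportal hepatocyte markers was -0.73 on replicate 3, and between -0.19 and -0.03 on the other arrays. Rasgrp3 had -4.54 on replicate 5 and between -0.45 and -0.12 on the other 3 arrays that measured it; replicate 5 is its only array with the mutant in Cy3, so the gap restates the dye coefficient it was named for. No explanation was tested for the periportal value.

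Arrays of like dye orientation correlated above those of opposite orientation, by 0.133 on average, and by 0.0724 after removal of the running median along probe number. Replicates 3 and 5 left unturned would give this pattern with a real mutant effect, but all 313 coded values on these arrays have the opposite sign to those on the other arrays, which argues that they had been turned. Dye bias left in the ratios may account for the pattern. The dye coefficients of neighbouring probe numbers correlated at 0.192, beyond the 0.0229 of shuffled orders, while the mutant coefficients did so at 0.007. By array, neighbouring ratios correlated at 0.221 on replicate 1 and 0.135 on replicate 5, and at 0.024, 0.033 and 0.060 on replicates 2, 3 and 4. The correlation along probe number thus lies mainly in replicates 1 and 5, which are of opposite orientation. It does not show a bias shared by all arrays of an orientation. With 10 choices of 2 of the 5 arrays, no share under 0.05 can be reached; the real choice gave 0.133 and the highest other 0.113. No biological explanation was tested, since both orientations hold mutant animals.

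The 6 lists with the lowest adjusted p (150 genes together) had a median of -0.15, against 0.03 for all genes. A trend of all genes with low spread is argued against as the whole cause, since random sets of other genes matched on spread had a typical median of 0.0274. Spread was used in place of brightness, which is not given in the sources used here. Whether spread tracks brightness was not shown, so a trend with brightness stays open. Members that vary together from array to array may account for the low p of the preset test in 4 lists. The estimated correlation was 0.429 for ribosomal proteins, 0.354 for oxidative phosphorylation, 0.572 for gluconeogenesis and 0.183 for the urea cycle. Each lay above the central 95% of random sets of its size. So did cholesterol synthesis at 0.392, the proteasome at 0.191 and secreted hepatocyte proteins at 0.161. Their camera adjusted p was 0.894, 0.908 and 0.396, so such a correlation does not by itself give a low p. In camera with an estimated correlation, the lowest adjusted p of any list was 0.758. That value does not bear on this explanation, since it was also reached by the circadian and periportal lists, with estimated correlations of -0.000983 and 0.0238. Whether members of the circadian and periportal lists vary together stays open, as 95% of random sets of their size lay between -0.102 and 0.229. An effect of the genotype was not called and stays open: the median was -0.28, -0.07, -0.04, -0.12 and -0.29 without replicates 1 to 5 in turn, and the pooled members' medians on replicates 1 and 5 were 0.21 and 0.03, and those on replicates 2, 3 and 4 were -0.44, -0.42 and -0.12.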

How the results depend on the processing

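Every alternative run gave 0 probes called for the mutant coefficient and for the dye coefficient. Keeping coded values, leaving out simple-fraction values, removing the running median and the preset correlation over genes on all 5 arrays were chosen after seeing the data. The 470 probes at an unadjusted p under 0.05 became 834 with replicates 3 and 5 turned (by construction the dye coefficient), 242 with values on all 5 arrays, 271 without simple-fraction values and 264 with probes averaged by gene, where fewer features were tested; leaving out each array gave 482 to 796, the highest without replicate 1. For the dye coefficient, 834 became 367 on all 5 arrays and 555 without simple-fraction values, and 828 to 1165 with each array left out. The median size of change on the 3 Cy5 arrays, 0.39, was 0.49 to 0.54 with each array left out, where 2 arrays are averaged. The 410 probes of these 3 arrays at an unadjusted p under 0.05 in limma became 428 to 773, the highest without replicate 4. More probes were tested there.

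The 0 lists called became 4 with values on all 5 arrays (urea cycle, ribosomal proteins, gluconeogenesis, periportal), 4 with the preset correlation on those genes, 1 with array weights (ribosomal proteins), 3 with coded values kept and 5 with probes as separate features; leaving out each array gave 0 to 4. Without replicate 1 the number was 4, without replicate 5 it was 1 and without the others 0; the cause was not tested. Camera with an estimated correlation and fry called 0.

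The 20 named genes were chosen for 1 sign on all 5 arrays, which largely fixes their sign under the other settings; 16 of 20 changed it with replicates 3 and 5 turned, none of them called. List medians changed sign in 71 of 489 values under the 15 other settings and in 24 of 33 with those arrays turned, and the direction of the list test in 43 and 25. The direction check ranged from the 55.9th to the 93.1st percentile with each array left out. It was 98.0 with values on all 5 arrays and 95.1 without simple-fraction values, past the bound of 95. These percentiles decide no direction, since variation independent between animals enters both coefficients alike. The difference between like and opposite pairs was 0.0999 with Spearman's rho and 0.0724 without the running median. No probe carried the name Pitx3, so the planned Pitx3 result could not be computed under any setting. Brightness over background is not given, so a brightness filter was not run.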

Other observations

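The test over list pairs was chosen before its result was seen and the sign-flip test after the list medians were seen.

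Probes of 4 lists of transcripts abundant in liver were measured on more arrays, and with less spread, than all probes together. The 267 probes of ribosomal proteins, oxidative phosphorylation, secreted hepatocyte proteins and the urea cycle had values on 4.10 arrays on average, against 3.57 for all probes, and a median SD between arrays of 0.60 against 1.18. Probes on all 5 arrays with at least 1 ratio of small whole numbers had a median SD of 0.78 and those with none 0.63. Some of these ratios may match by coincidence. Albumin, Alb, the main plasma protein of hepatocytes, was counted at a ratio of nearly, not exactly, 1 before scaling on 3 arrays, by the bounds below (-0.34, -0.14 and -0.08 on replicates 2, 3 and 5, the array constants being -0.33, -0.15 and -0.08). In all, 6 probes lay between 0.001 and 0.02 (log2) from the constant on at least 3 arrays, values closer than that not being counted, where 0.07 would by chance; Fam110b did so on all 5. Coded values fell on at least 2 arrays for 20 probes, where 11.7 would by chance, and on at most 2.

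Pericentral hepatocyte markers lay above periportal ones, by list median, on 5 of 5 arrays, and by list mean on 4 of 5, with -0.63 on replicate 1 and 0.45 to 1.15 on the others. The mean difference was 0.48 ± 0.67 (SD, n = 5), and 0.40 to 0.58 with each of the 19 genes left out in turn. A shift between the zones of the liver lobule in the mutant is a hypothesis only: the exact two-sided sign-flip test gave p = 0.25, where the smallest p that 5 arrays allow is 0.0625. A choice among many pairs may account for it, since 23.1% of the 528 pairs of lists had a mean difference as large relative to its error. By list mean, 31 of these pairs had 1 sign on all 5 arrays, where 33 would if arrays were independent. The pericentral and periportal pair, at 4 of 5 by list mean, is not among them, and pairs were not counted by list median.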
